A study of Mus musculus with 8 samples.

How the data were processed

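The series holds 8 one-colour Affymetrix arrays of mouse ES cells, 4 with luciferase esiRNA and 4 with Ctr9 esiRNA, all taken on day 4. Total RNA was column-purified, treated with DNase and labelled with biotin by a one-cycle procedure, per the labels' protocols. The deposited values are log2 probe set signals. GCOS 1.4 and RMA are the tools named in the submitters' processing notes; the settings and the annotation behind the values are not given in the sources used here. RMA subtracts a background and equalises the arrays' distributions, so differences of low signals are compressed and a change shared by all genes would not be seen. The log2 values were used as deposited, without further scaling or filter.

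The table holds 45101 probe sets. The 64 control probe sets of the manufacturer were kept out of the comparison, which leaves 45037. Among these, 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 are unnamed here. Symbols were updated through the Entrez identifiers of the GRCm38.p6 gene table, which held 34741 of the 1-symbol probe sets; only names were used from it. Each of 18193 genes was read by its 1-symbol probe set with the highest mean over the 8 arrays. Among the tested probe sets, 456 values are empty, never more than 1 per probe set, and the fit used the values left. For tests of gene lists and for means over a gene's probe sets, which need a value in every array, an empty value was filled with the mean of its group.

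Groups were compared per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. SE is limma's moderated standard error. Bootstrap intervals of list medians resampled the genes of a list, which takes them as independent and holds no spread between arrays. For Ctr9 and for the RNA quality controls an exact two-sided permutation test over the 4 against 4 values is given, whose smallest p is 0.0286. Gene lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 23 lists. With an estimated correlation, the calls of the pluripotency, trophectoderm, actin and mesenchymal, and imprinted lists held, and those of the other 9 lists past the threshold did not. The design, the gene lists and the rule for named genes were set before the data were examined. Of 554 list members, 516 had a named probe set, 4 of them under an older symbol. The gene T, which the rule names, had no probe set with 1 symbol here. Named are the Paf1 complex members, a fixed set of lineage genes, the 10 largest increases and 10 largest decreases among genes that passed with groups that do not overlap, and up to 4 members per list with the smallest adjusted p. Ctr9 is the named gene whose probe sets pass in opposite directions.

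The fit was tested on simulated arrays for the comparison of Ctr9 with luciferase esiRNA, with the means and spreads of the 45037 probe sets and 200 changed ones. All 50 changed by 1 log2 unit were found (100%), against 58% at 0.5, 28% at 0.3 and 6% at 0.2, with 1 false call among 97. Camera found the planted list and called none of 40 unchanged lists. The simulated probe sets were drawn independently, so this cannot show how camera's preset correlation serves lists of correlated genes. Few changes were present in that simulation, so its threshold was stricter than in the real comparison.

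Alternatives were filters on dim probe sets, other scalings (median centring, quantile, cyclic loess), a trended robust prior, array weights, the replicate number as a block, leaving out each array, stricter thresholds, the mean of a gene's probe sets, and other gene list tests (estimated correlation, fry, ranks). Chosen after seeing the data were probe sets with all 8 values and leaving out luciferase arrays 1 and 2 or 3 and 4, since the control arrays lie in 2 pairs on the second principal component (8.93% of the variance, against 62.3% on the first, which separates the treatments). For explanations weighed in the closing part, the bounds first written for each test decide its reading. For cells that took up no esiRNA a lower bound was also tried once the values were known, and both counts are given; the fibroblast test is read from the rise the explanation needs, since its interval spans the lower bound written for it. Figures were drawn with matplotlib 3.10.9.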

Results

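RNA from mouse embryonic stem (ES) cells was measured on 8 Affymetrix arrays, 4 from cells given an esiRNA against Ctr9 and 4 from cells given an esiRNA against luciferase, a transcript that these cells do not make and that served as the transfection control. An esiRNA is a pool of short double-stranded RNAs made from 1 longer transcript, here delivered by lipofection, and the samples were taken on day 4. The cells carry the strain label Oct4-Gip. Ctr9 is a scaffold subunit of the Paf1 complex, which travels with RNA polymerase II during elongation. The comparison asks which transcripts differ between the 2 treatments. The upper quartiles of the arrays lay between 8.10 and 8.15 on the log2 scale, and arrays of 1 group correlated at 0.997 to 0.998 over probe sets, against 0.992 to 0.994 between groups. No label says whether the 4 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

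The target itself was only weakly lower. The brightest of 5 Ctr9 probe sets read 10.20 ± 0.058 (SD, n = 4) in the luciferase arrays and 10.11 ± 0.027 (SD, n = 4) in the Ctr9 esiRNA arrays, a log2 difference of -0.09 (SE 0.047), which did not pass the test (exact two-sided permutation p = 0.0857, where 0.0286 is the smallest that 4 against 4 allows; limma, Benjamini-Hochberg adjusted p = 0.209). The next brightest Ctr9 probe set fell by 0.15 (SE 0.048, limma adjusted p = 0.0398) and the third fell by 0.18 (SE 0.053, limma adjusted p = 0.0279), a change of -11.9%. A dim Ctr9 probe set, at 5.90 with luciferase esiRNA, went the other way and rose by 0.29 (SE 0.080, limma adjusted p = 0.0228), and the dimmest differed by 0.27 (SE 0.116, limma adjusted p = 0.125). The mean over all 5 probe sets differed by 0.027, so the direction for Ctr9 depends on the probe sets taken. The groups below are therefore those that the labels name, and the part of the transcript that the esiRNA covers is not given in the sources used here.

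**Figure D1:**
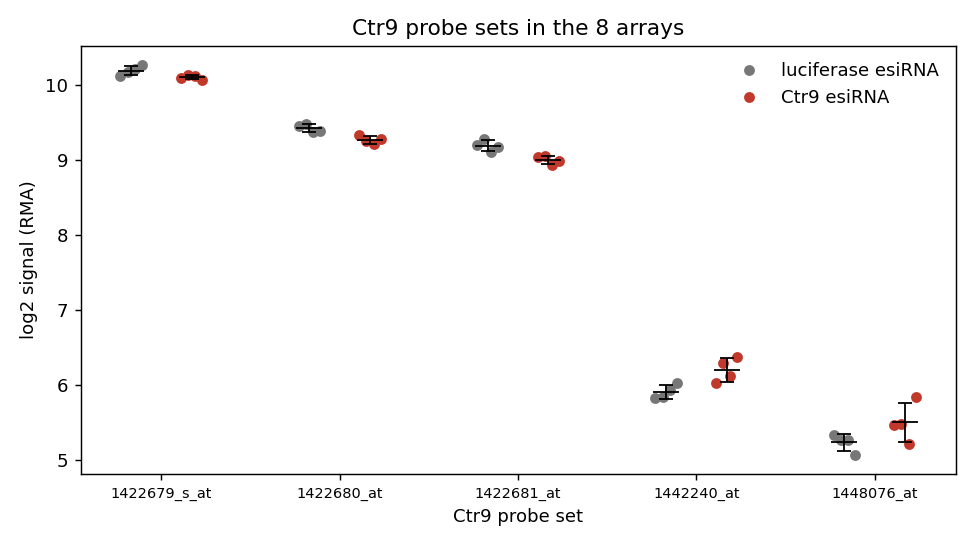
Log2 signal (RMA) of the 5 Ctr9 probe sets in each of the 4 luciferase esiRNA arrays (grey) and 4 Ctr9 esiRNA arrays (red), with mean and SD (black). The 3 bright probe sets read slightly lower with Ctr9 esiRNA and the 2 dim ones slightly higher.

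Among the other Paf1 complex genes, Cdc73 rose by 0.28 (SE 0.052, limma adjusted p = 0.003) on the brightest of its 7 probe sets, and the other 6 Cdc73 probe sets did not pass, which leaves its mean over probe sets at 0.028. Paf1 (0.12, SE 0.048), Wdr61 (0.11, SE 0.045), Leo1 (-0.08, SE 0.049) and Rtf1 (0.03, SE 0.054) did not pass. Of 27 measured genes of elongation and the histone modifications that accompany it, 10 fell and 2 rose, with 10 and 3 adjusted over the list alone. Rbbp5 (-0.49, SE 0.043) and Ash2l (-0.31, SE 0.044), subunits shared by H3K4 methyltransferase complexes, fell, as did Ell (-0.36, SE 0.051), an elongation factor, while Ube2b (0.36, SE 0.045), a ubiquitin-conjugating enzyme for histone H2B, rose. The calls of Ell and Ube2b rest on their brightest probe sets and ended with the mean of all their probe sets (-0.10 and 0.074). Neither the elongation list nor the Paf1 list passed as a whole (camera, Benjamini-Hochberg adjusted p = 0.0629 and 0.491). The elongation list did pass without luciferase replicate 1 (0.0414) or 2 (0.0408), and its camera adjusted p ran from 0.0142 to 0.351 over 22 alternatives, the highest with an estimated correlation.

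Changes across the array were broad and mostly small. Of 45037 probe sets tested, 5304 were higher and 5905 lower in the Ctr9 esiRNA arrays (24.9% in all). Among 18193 genes, each read by its brightest probe set, 2873 were higher and 2727 lower. The median change of the genes that passed was 1.24-fold. A change of at least 2-fold was found for 184 higher and 60 lower genes. The 4 values of each group did not overlap for 28.6% of probe sets, against 2.86% by chance. Of all genes that passed, 5348 had groups that did not overlap. The rule for naming favours such genes, and all 105 genes named here that passed were among them. With luciferase esiRNA, 13 of these 105 genes read below the array median, among them Fgf5, Has2, Foxa2, Oasl2 and Plac1. Of these 13 genes, 12 were higher. RMA compresses differences of low signals and no background level was measured here, so the sizes of those changes are uncertain. Their directions rest on the same low signals and were not tested in another way. Of 9010 genes with several probe sets, 192 had probe sets that passed in opposite directions.

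The genes with the largest increases included Car4, a carbonic anhydrase, at 2.94 (SE 0.097, 7.66-fold), the uncharacterised transcript 3830417A13Rik at 2.91 (SE 0.063), the growth factor Igf2 at 2.79 (SE 0.081), the keratins Krt8 at 2.61 (SE 0.071) and Krt18 at 2.39 (SE 0.045), the growth factor Fgf5 at 2.57 (SE 0.102) and the hyaluronan synthase Has2 at 2.55 (SE 0.155). The guanylate binding proteins Gbp2b (2.57, SE 0.047), Gbp2 (5.67-fold) and Gbp3 (2.46, SE 0.079) completed the 10. The largest falls were those of the stress-induced Nupr1 (-2.06, SE 0.095), the activin subunit gene Inhbb (-1.90, SE 0.064), Triml1 (-1.78, SE 0.086), the retinoic acid responsive Stra8 (-1.71, SE 0.087), the transcription factor Tbx3 (-1.64, SE 0.061), Lrrc31 (-1.60, SE 0.166), the water channel Aqp3 (-1.46, SE 0.054), the adhesion receptor Adgrd1 (-1.46, SE 0.094), the peptidase Dpp4 (-1.45, SE 0.066) and Maats1 (-1.43, SE 0.060). The other Inhbb probe set differed by only -0.34, so the size of that fall rests on the brightest one. Other probe sets also changed less for Fgf5 (1.01, at similar brightness), Has2 (1.80) and Igf2 (0.74, dim). The same held for dimmer probe sets of Tbx3, Aqp3, Dpp4 and Maats1 (for Maats1 -0.03, which did not pass). Those of Car4, Krt8 and Gbp2 changed by similar sizes.

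Genes of the pluripotent state were lower as a group. Of 36 measured members, 22 fell, 5 rose and 9 did not pass, with 23 lower and 5 higher adjusted over the list alone, and the list's median was -0.40 (camera, Benjamini-Hochberg adjusted p = 2.17e-08; adjusted p = 0.0226 with an estimated correlation). The members with the smallest adjusted p were Tbx3 (above), Nr0b1 (-1.14, SE 0.049), Tcl1 (-0.97, SE 0.051) and Tfcp2l1 (-0.92, SE 0.043), all of which fell. Nanog fell by 0.44 (SE 0.044), from 13.27 ± 0.043 to 12.84 ± 0.029 (SD, n = 4 each), and Pou5f1, which encodes Oct4, fell by 0.20 (SE 0.042, limma adjusted p = 0.00564). Sox2 differed by -0.11 (SE 0.057) and did not pass. The Pou5f1 call ended when luciferase arrays 3 and 4 were left out (limma adjusted p = 0.0508).

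Genes typical of the primed, post-implantation epiblast rose in 11 of 15 cases and 1 fell, with 11 and 4 adjusted over the list alone, at a list median of 0.65 (camera adjusted p = 1.23e-05; adjusted p = 0.103 with an estimated correlation). Fgf5 went from 4.74 ± 0.125 to 7.31 ± 0.210 (SD, n = 4 each) on its brightest probe set. The Wnt receptor gene Fzd2 (1.98, SE 0.068), the POU factor gene Pou3f1 (1.94, SE 0.058) and the de novo DNA methyltransferase gene Dnmt3b (1.52, SE 0.052) also rose.

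Trophectoderm markers were higher in 14 of 23 cases, with 1 lower (14 and 2 adjusted over the list alone), at a median of 0.54 (camera adjusted p = 5.48e-06; adjusted p = 0.0226 with an estimated correlation). The epithelial keratins Krt8, Krt18 and Krt19 (1.63, SE 0.092) and the placental gene Plac1 (2.82-fold) led the list. Cdx2, a transcription factor of the trophectoderm lineage, rose by 1.39 (SE 0.094), from 5.82 ± 0.145 to 7.21 ± 0.166 (SD, n = 4 each). The keratins are also made by other epithelia.

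**Figure D2:**
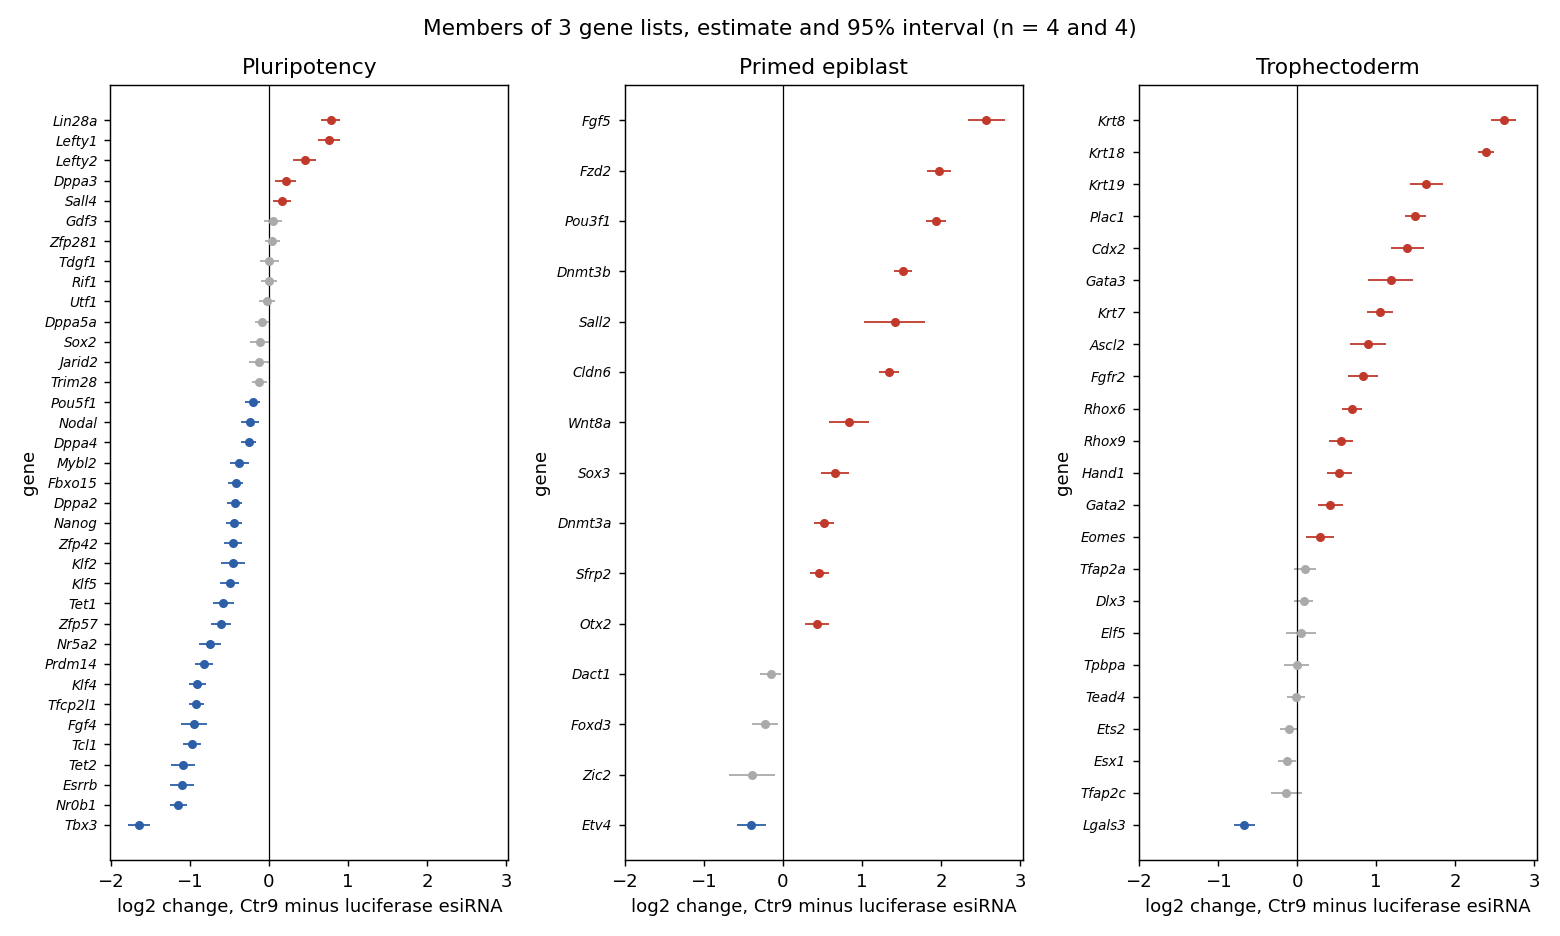
Log2 change (Ctr9 minus luciferase esiRNA) of each measured member of the pluripotency, primed epiblast and trophectoderm lists, with 95% intervals from limma. Red marks genes that rose, blue genes that fell and grey genes that did not pass; 22 of 36 pluripotency genes fell, while 11 of 15 primed epiblast and 14 of 23 trophectoderm genes rose.

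Markers of other lineages were read list by list, and no test compared these lists with those above. Of 27 neuroectoderm genes, 10 rose and 3 fell (11 and 4 adjusted over the list alone). The list median was 0.086 and the camera adjusted p = 0.0327, which became an adjusted p = 0.175 with an estimated correlation and 0.0538 without Ctr9 esiRNA replicate 1. Over 22 alternatives the camera adjusted p ran from 0.0158 to 0.230, the highest among probe sets above the median signal. Sox11 (1.93, SE 0.072), Sox1 (1.33, SE 0.075) and the neurofilament gene Nefm (0.78, SE 0.068) rose, while Pax6 fell by 0.79 (SE 0.069). The other, less bright Sox1 probe set differed by 0.027 and did not pass. Among 27 primitive and visceral endoderm genes, 9 rose and 4 fell (9 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.249). Foxa2 (1.98, SE 0.169), the endocytic receptor gene Lrp2 (1.51, SE 0.094) and its adaptor Dab2 (1.26, SE 0.073) rose, and the laminin gene Lama1 fell by 1.07 (SE 0.082). Gata6 read 5.04 ± 0.111 and 4.92 ± 0.125 (SD, n = 4 each), a difference of -0.12 that did not pass. Of 27 primitive streak and mesoderm genes, 4 rose, among them Fgf8 (1.63, SE 0.136) and Msx2 (0.65, SE 0.094), and 4 fell, among them Bmp4 (-0.56, SE 0.049) and Gsc (-0.44, SE 0.073). Adjusted over the list alone these were 5 and 4, and the list did not pass (camera adjusted p = 0.650). Of 33 Hox genes 5 rose and none fell (4 and 0 adjusted over the list alone), with Hoxb2 (0.60, SE 0.095), Hoxb13 (0.52, SE 0.092), Hoxb1 (0.39, SE 0.077) and Hoxa2 (0.24, SE 0.067) first among them, and the list did not pass (camera adjusted p = 0.567). Hoxa2 lost its call without luciferase replicate 2 (limma adjusted p = 0.0636) or 3 (0.0695) and without Ctr9 esiRNA replicate 1 (0.0651) or 3 (0.0685).

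Germ cell genes fell in 10 of 19 cases and rose in 4 (the same counts adjusted over the list alone), at a median of -0.20 (camera adjusted p = 0.0334; adjusted p = 0.209 with an estimated correlation, the highest of 22 camera alternatives, with 0.0210 the lowest). It was 0.0518 with luciferase arrays 1 and 2 left out and 0.0612 on ranks. Stra8, the receptor gene Kit (-0.84, SE 0.045) and the RNA-binding protein gene Dazl (-0.70, SE 0.047) fell, and the helicase gene Ddx4 rose by 0.75 (SE 0.044). Fibroblast genes, a marker list for feeder cells, had a median of 0.099, with 6 of 24 higher and none lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.00985; adjusted p = 0.266 with an estimated correlation). Bgn (0.75, SE 0.106), Col5a2 (0.74, SE 0.093), Mmp2 (0.42, SE 0.047) and Twist1 (0.41, SE 0.057) rose.

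The actin cytoskeleton and mesenchymal list gave the smallest p of all 23 lists. Of 26 members, 21 rose and 3 fell (21 and 3 adjusted over the list alone), at a median of 0.76 (camera adjusted p = 1.89e-10; adjusted p = 0.0226 with an estimated correlation). The matricellular protein genes Ccn1 (1.68, SE 0.051) and Ccn2 (1.34, SE 0.048), the annexin gene Anxa1 (1.39, SE 0.056) and the tropomyosin gene Tpm1 (1.21, SE 0.053) led it. The fibroblast list, a marker of mixed-in feeder cells, had a median of 0.099, with 18 of its 24 members not past the test (camera adjusted p = 0.00985; adjusted p = 0.266 with an estimated correlation). Imprinted genes rose in 14 of 17 cases and 1 fell (14 and 1 adjusted over the list alone), at a median of 0.68 (camera adjusted p = 9.03e-10; adjusted p = 0.0226 with an estimated correlation). Igf2 went from 8.73 ± 0.169 to 11.51 ± 0.074 (SD, n = 4 each), and the cell cycle inhibitor gene Cdkn1c (1.76, SE 0.062), Nnat (1.52, SE 0.045) and Peg3 (0.81, SE 0.054) rose.

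Signalling and metabolic lists also shifted. Cholesterol synthesis genes rose in 13 of 16 cases and none fell (13 and 0 adjusted over the list alone), at a median of 0.54 (camera adjusted p = 1.33e-08; adjusted p = 0.130 with an estimated correlation), among them Dhcr7 (0.91, SE 0.071), Idi1 (0.75, SE 0.057), Sqle (0.72, SE 0.049) and Cyp51 (0.71, SE 0.050), all enzymes of the pathway. Of 17 genes of FGF and ERK signalling, 8 rose and none fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.000362; adjusted p = 0.175 with an estimated correlation), with Phlda1 (0.88, SE 0.066), the ERK phosphatase gene Dusp6 (0.72, SE 0.060), Spry1 (0.51, SE 0.046) and Ccnd1 (0.49, SE 0.049) first. Of 15 Wnt targets, 8 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.000313; adjusted p = 0.175 with an estimated correlation), led by Lef1 (1.24, SE 0.067), Ascl2 (0.89, SE 0.102), Dkk1 (0.83, SE 0.086) and Bambi (0.37, SE 0.053). Glycolysis and hypoxia genes rose in 13 of 23 cases and fell in 3 (13 and 3 adjusted over the list alone; camera adjusted p = 0.00879; adjusted p = 0.528 with an estimated correlation, the highest of 22 camera alternatives, with 8.16e-05 the lowest). It was 0.0856 with luciferase arrays 3 and 4 left out. The glucose transporter gene Slc2a1 (0.53, SE 0.046), Tpi1 (0.52, SE 0.050) and Ldha (0.41, SE 0.049) rose, and the phosphofructokinase gene Pfkp fell by 0.64 (SE 0.067).

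Of 19 genes of LIF, BMP and Nodal signalling, 9 rose and 6 fell (9 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.166). Its largest changes were those of the BMP-responsive inhibitors Id2 (2.33, SE 0.091), Id1 (1.49, SE 0.057) and Id3 (1.22, SE 0.067, n = 3 luciferase values). Skil rose by 0.61 (SE 0.046). Interferon response genes rose in 13 of 26 cases and fell in 3 (13 and 4 adjusted over the list alone), at a median of 0.24 (camera adjusted p = 0.00237; adjusted p = 0.0666 with an estimated correlation). Over 22 alternatives the camera adjusted p ran from 0.00116 to 0.209, the highest among probe sets above the median signal. Oasl2 (1.98, SE 0.118), the immunoproteasome subunit gene Psmb8 (1.78, SE 0.077), Bst2 (1.10, SE 0.057, n = 3 Ctr9 esiRNA values) and Ifi35 (1.02, SE 0.052) rose.

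The remaining lists did not pass. Of 34 cell cycle genes, 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.680; the list's median was -0.0026 while its mean, 0.031, and the test pointed up), with Ccne2 at 0.58 (SE 0.072), Rrm1 at 0.33 (SE 0.045), Ccne1 at 0.29 (SE 0.052) and Kif20a at 0.17 (SE 0.045). Kif20a lost its call without luciferase replicate 3 (limma adjusted p = 0.0522) or Ctr9 esiRNA replicate 4 (0.0588). Of 22 p53 targets, 2 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.166), with Ddit4 at 0.64 (SE 0.081), Mdm2 at -0.41 (SE 0.056), Sesn2 at -0.34 (SE 0.064) and Ei24 at -0.29 (SE 0.047). Of 26 Myc and ribosome biogenesis genes, 6 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.385), with Mycn at 0.31 (SE 0.053), Nop16 at 0.28 (SE 0.056, n = 3 Ctr9 esiRNA values), Odc1 at 0.21 (SE 0.040) and Nop58 at -0.30 (SE 0.045). Among 11 reference genes, 2 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.233): B2m by 0.41 (SE 0.040) and Gusb by 0.19 (SE 0.049) were higher and Sdha fell by 0.13 (SE 0.042), while Polr2a differed by -0.25 (SE 0.083) without passing. The Sdha call ended with arrays centred on their medians (limma adjusted p = 0.0541) and without any 1 of the 8 arrays (0.0588 to 0.103), although a less bright Sdha probe set fell by 0.37 (limma adjusted p = 0.000184). The Gusb call ended without Ctr9 esiRNA replicate 2 (0.0550) or 3 (0.0537).

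**Figure D3:**
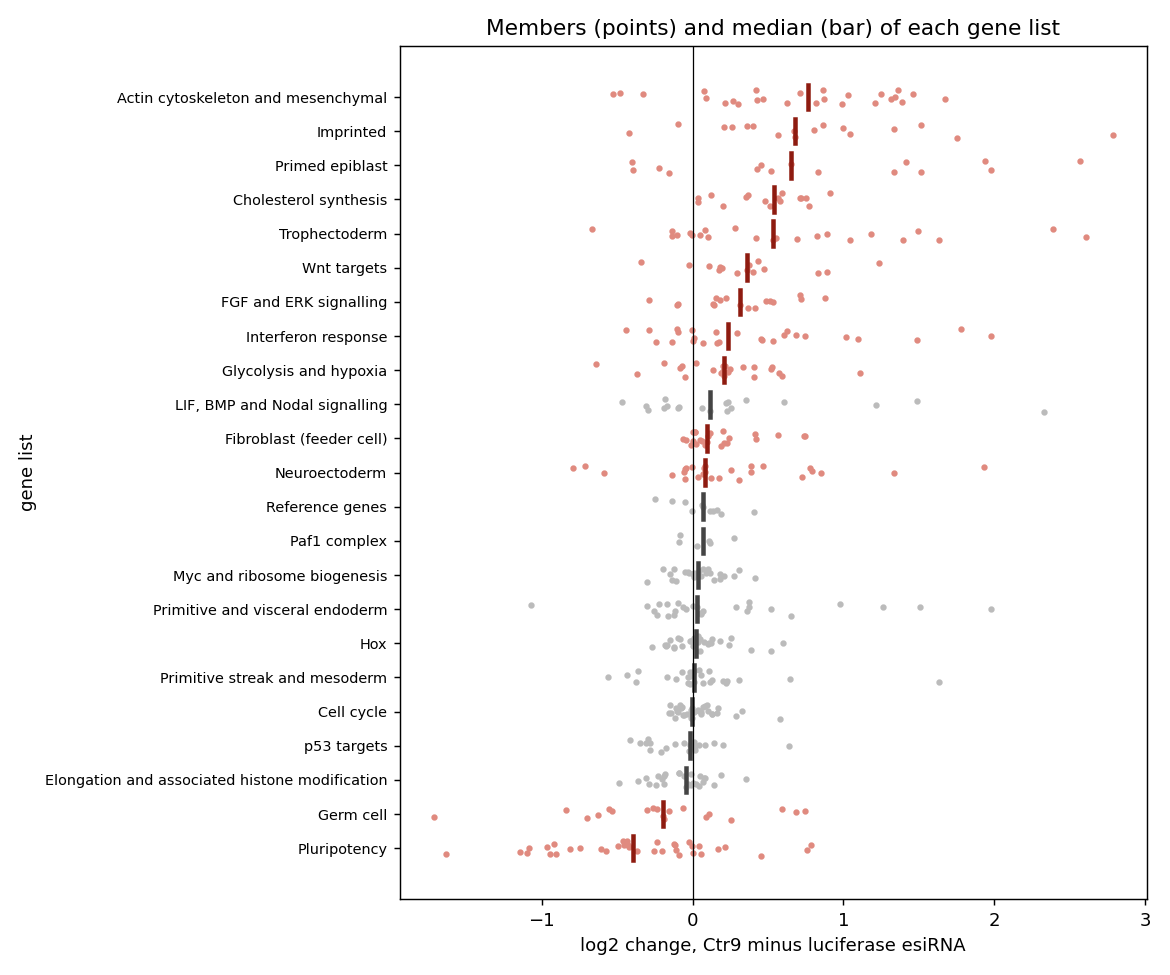
Log2 change (Ctr9 minus luciferase esiRNA) of the measured members of the 23 gene lists; each point is a gene and each bar the list's median. Lists past the camera threshold are in red and the others in grey, and the medians run from -0.40 for pluripotency to 0.76 for the actin cytoskeleton and mesenchymal list.

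RNA quality was read from control probe sets. The 3' minus 5' difference of the Gapdh control was -0.019 ± 0.0060 in the luciferase arrays and -0.017 ± 0.021 in the Ctr9 esiRNA arrays (SD, n = 4 each; exact two-sided permutation p = 0.886), and that of beta-actin was 0.228 ± 0.026 and 0.231 ± 0.030 (SD, n = 4 each; exact permutation p = 0.914). Both controls read near the highest values of the arrays, where differences can be flattened. For the transferrin receptor control, which reads lower, it was 0.856 ± 0.053 and 0.944 ± 0.057 (SD, n = 4 each; exact permutation p = 0.114).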

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

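The tests of the Ctr9 fall, of RNA quality and of the guanylate binding protein subset, with and without the members seen first, were chosen only after the result was seen. The subset lists of interferon genes were also written after the data were seen.

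Of the 35 ways to split the 8 arrays into 4 and 4, 1 gave as many probe sets as the real split, the real one itself (11209 probe sets); the highest of the others gave 0 by limma after adjustment and 2925 at an unadjusted p under 0.05, against 15844 in the real split. The share of 1 of 35 is the smallest these splits allow. The other splits mix the treatments, which widens their groups and lowers their counts. No label says whether the samples are separate cultures, so a chance difference between cultures was not tested. None of this separates the esiRNA from anything else the samples of a group share.

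The first pattern is a fall of Ctr9 that is small beside the other changes. It is a fall of the brighter probe sets, while a dim one rose by 0.29. Whether or not they passed, 57.6% of genes differed by more than the brightest Ctr9 probe set, which includes differences within the spread. Only 30.8% of genes passed. If cells that took up no esiRNA held back the fall, no gene could fall by a clearly larger share. By over 5 times the share of the brightest Ctr9 probe set, 487 genes fell. That probe set did not pass (95% interval from -0.19 to 0.015), so a multiple of its fall is not stable. Against the Ctr9 probe set that fell most, 16 genes fell by over 5 times its share, fewer than the bound first written asked. At over 3 times its share, a bound tried once the values were known, there were 274. The 95% intervals of 676 genes lay below that of every Ctr9 probe set, which argues against such cells as the whole cause. That count was not among the bounds first written. Of 1693 genes in the signal range of the brightest Ctr9 probe set, 53 passed with falls of over 0.5 log2, so such falls could be read at that level. That probe set read well above the array median, so compression of low signals was hardly in question for it. Probe sets that read different parts of the transcript would need 1 that fell by over 0.5 log2. The lowest interval bound of any Ctr9 probe set was -0.30, which argues against such a fall in the parts these probe sets read. None of the 4 above the array median fell by 0.25, the bound written against it, although the interval of the largest fall (-0.18, from -0.30 to -0.066) spans -0.25. The opposite directions of bright and dim probe sets stay unexplained. A biological explanation such as recovery of Ctr9 by day 4 stays open, since no earlier time was measured.

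The second pattern is the rise of interferon response genes. Both treatments deliver double-stranded RNA, so a reaction to it raises sensor and type I interferon genes here only if stronger with Ctr9 esiRNA. Their median was 0.15 (95% bootstrap interval over genes from -0.0024 to 0.46). Of 21 genes, 8 were higher and 3 lower (Xaf1 at -0.44, Oas1a at -0.29 and Ddx58 at -0.24). The interval lies under the 0.5 set for a strong difference in reaction. The median itself lay below the 0.25 set as the lower bound, and 8 of 21 is under the share asked. The estimates thus met the bounds written against the explanation. Since the interval spans 0.25, a weaker difference in reaction stays open. Guanylate binding protein, immunity GTPase and antigen processing genes had a median of 1.12 with 15 of 20 higher, and the medians differed (permutation p = 0.00647, two-sided, genes taken as exchangeable although they are not independent). The values of 6 of them (Gbp2, Gbp2b, Gbp3, Gbp7, Irgm1 and Psmb8), and of Oasl2 in the sensor subset, had been seen when the subsets were written; without these 7, the medians were 0.65 with 9 of 14 higher and 0.11 with 7 of 20 higher (permutation p = 0.0292, two-sided). More members of the sensor subset than of the second read low with luciferase esiRNA. Mx1 (3.60), Ifit1 (3.70) and Ifnb1 (4.38) did so in the first, and Gbp8 (3.28) and Nlrc5 (3.93) in the second. RMA compresses differences of low signals, so the contrast of the subsets is not separated from signal level. A response weighted toward the second subset is a hypothesis found on the same data.

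The third pattern is the rise of differentiation markers. Fibroblast feeder cells would raise their abundant genes, a median above 0.5, but the fibroblast median was 0.099 (95% bootstrap interval over genes from 0.020 to 0.21). That median argues against feeder cells as the source of rises of this size, although the interval spans the 0.1 set as the lower bound. Named outside the rule, Col1a1 (5.39), Col3a1 (4.11) and Lum (4.21) read low with Ctr9 esiRNA and differed by 0.049, -0.012 and 0.0041. Other members went the other way: 6 of 24 were higher and none lower, among them Bgn (0.75) and Col5a2 (0.74). The list passed (camera adjusted p = 0.00985), though not with an estimated correlation (0.266). A small share of feeder cells therefore stays open. With luciferase esiRNA, 10 of the 24 genes already read above the array median, and none is on another list. The 3' minus 5' values of Gapdh and beta-actin, which differed by at most 0.0025, decide nothing on RNA quality, since both read within 1 log2 unit of the arrays' highest values. Among controls below that ceiling, the transferrin receptor differed by 0.088 (95% interval from -0.0069 to 0.18) and pyruvate carboxylase by 0.0020 (from -0.16 to 0.16, n = 4 and 3), which argues against a loss of over 0.2 but leaves a smaller one open. A change of cell state after Ctr9 esiRNA stays open and was not tested, as do other cell types mixed in.

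In 10 of 223 groups of 4 values of named genes (4.48%, where chance gives about 5%), 1 array stood far from the others, measured as its gap over the group's range. With luciferase esiRNA these were Polr2a (0.907, array 2), Plac1 (0.867, array 4), Ube2b (0.861, array 1), Ccn2 (0.857, array 4) and Sdha (0.833, array 1). With Ctr9 esiRNA they were Wdr61 (0.916, array 2), Pfkp (0.888, array 1), Ddx4 (0.862, array 2), Ccn1 (0.837, array 3) and Lama1 (0.834, array 1). Among the 64 control probe sets outside the comparison, 4 were higher with Ctr9 esiRNA: 3' beta-actin by 0.13, middle beta-actin by 0.15, 3' Gapdh by 0.087 and 5' Gapdh by 0.086. The 3 that were lower read pyruvate carboxylase and changed by -0.24 for the 3' and 5' probe sets and -0.34 for a middle one. These sizes cannot be ranked against those of Gapdh and beta-actin, which read near the highest values of the arrays.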

How the results depend on the processing

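The controls 1 and 2 or 3 and 4 were left out, and probe sets with all 8 values taken alone, only after seeing the data. Counts of probe sets and genes stayed within 1.5 times under every filter, scaling, prior, weight and left-out array or pair of controls run. Without 1 array each, 4539 to 4839 probe sets were higher and 4902 to 5296 lower, and 2463 to 2650 genes higher and 2267 to 2428 lower. The replicate number as a block gave 4606 and 5165 probe sets and 2477 and 2296 genes; same-numbered arrays did not deviate together (correlations from -0.078 to 0.063, 4 of 8 arrays closest to their own number), so the numbers were not taken as pairs. By construction, stricter thresholds gave fewer: at an adjusted p under 0.01, 3389 and 3611 probe sets and 1902 and 1758 genes; at 2-fold or more, 289 and 108 and 184 and 60; with limma's treat against 1.2-fold, 1230 and 1055 and 728 and 553. The Ctr9 difference ranged from -0.11 to -0.066 without 1 array each and reversed to 0.027 with the mean of its probe sets, which holds the 2 dim ones. Rtf1, not called, reversed to -0.018 with controls 3 and 4 left out; the cause was not tested.

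Adjusted p of gene lists that crossed the threshold, cause not tested: among probe sets above the median signal, neuroectoderm 0.230 and interferon 0.209; with the mean of probe sets, elongation 0.0210; without 1 array each, elongation from 0.0408 to 0.119 and neuroectoderm from 0.0182 to 0.0538; with an estimated correlation, primed epiblast 0.103, neuroectoderm, FGF and ERK, and Wnt 0.175 each, fibroblast 0.266, germ cell 0.209, interferon 0.0666, glycolysis 0.528 and cholesterol 0.130; on ranks, germ cell 0.0612; with controls 1 and 2 left out, elongation 0.0142 and germ cell 0.0518; with controls 3 and 4 left out, glycolysis 0.0856. With fry, which does not compare a list with other genes, Paf1 gave 0.0135, elongation 0.00241, endoderm 8.33e-05, cell cycle 0.0134, Myc 0.0488, LIF, BMP and Nodal 1.32e-05 and reference genes 0.000196. The stricter thresholds were applied to the counts alone and not to named genes, and a filter that dropped a gene gave no value for it. Of 2089 values of named genes with a call, 32 lost the call and 0 reversed. Of the 105 named genes with a call, 97 kept it under every alternative run that held them. The others were Cdc73, Ell and Ube2b with the mean of probe sets, Pou5f1 with controls 3 and 4 left out, Sdha with median centring and without any 1 array, Hoxa2 without luciferase array 2 or 3 or Ctr9 array 1 or 3, Gusb without Ctr9 array 2 or 3 and Kif20a without luciferase array 3 or Ctr9 array 4; the last 4 also lost it with either pair of controls left out, and Sdha, Gusb and Kif20a with the block. Elongation crossed without luciferase array 1 (0.0414) or 2 (0.0408) and neuroectoderm without Ctr9 array 1. No background level was measured here, so the signal below which a change is compressed is not known.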

Other observations

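The tests of the ATF4 list and of the empty values were chosen only after the result was seen.

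Genes of the amino acid and integrated stress response were lower with Ctr9 esiRNA. On a list of ATF4 targets written after Nupr1, Chac1, Ddit3 and Atf5 had been seen among the falls, 28 of 34 members fell and none rose (median -0.51). Without those 4, 24 of 30 fell and none rose, at a median of -0.44 (95% bootstrap interval over genes from -0.55 to -0.34). Camera gave p = 1.49e-15, and p = 0.0208 with an estimated correlation. Of the 30, those named here were picked after the list was tested: the pseudokinase gene Trib3 (-1.10), the folate enzyme gene Aldh1l2 (-0.91), the alanyl-tRNA synthetase gene Aars (-0.79) and the asparagine synthetase gene Asns (-0.54). A lower activity of this pathway may underlie these falls, as a hypothesis; amino acid supply was not measured.

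The empty values may come from the removal of single outlying values within a group before deposit. The 3 values left had a median range at most 0.040 times that of 3 values from complete groups (0.0060 against 0.16 with luciferase esiRNA and 0.0061 against 0.15 with Ctr9 esiRNA), and no complete group had an outermost gap above 0.949 of its range. No source used here describes such a step. Where a value was removed in this way, the spread of the group would be understated.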
